A study of Mus musculus with 8 samples.

How the data were processed

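Total RNA from the first lobe of the right lung was labelled with biotin and hybridized to single-colour Affymetrix expression arrays, per the labels' protocols. The table used here held 1 value per probe set and array. The authors' deposited values are read as log2 signals; RMA is named in the submitters' processing notes, with no version or settings, and the log base and any offset are not given in the sources used here. All columns held the same sorted values (largest SD across arrays 0), as quantile normalization leaves them. The median was -0.628, below 0, so the values carry an offset that is not explained. The hybridization spikes, added at increasing published concentrations, rose by 0.772, 0.825 and 0.68 units per doubling, where natural logarithms would give at most 0.693. If the base were another, every difference given as log2 would change by 1 factor, while tests, directions and calls at an adjusted p would not. Only the counts at a log2 difference of at least 1 would then differ.

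The table held 45101 probe sets, of which 64 were control probe sets and 8 had a missing value and were left out. Gene names came from a table of the platform's annotation: 34945 probe sets had 1 gene symbol, 932 several and 9160 were not listed and are unnamed here. Of 34958 listed probe sets with 1 symbol, 34754 had a gene ID found in a RefSeq table of assembly GRCm38.p6, used for names only. A probe set was kept if its value was at or above the array median on at least 2 of the 8 arrays, without regard to group. This left 27363 probe sets, 23304 with 1 symbol, for 13853 genes. Each gene was represented by its probe set with the highest mean over all arrays; 5808 genes had more than 1 passing probe set, and 1537 were measured by a probe set that can bind related transcripts. Further passing probe sets were compared for called genes among a day's largest rises and falls, named by the rule below. Called genes among the 7 largest differences of any fixed list, whether or not it passed its test, were compared too. Of those with further probe sets, 6 of 33 on day 1 and 6 of 31 on day 7 had at least 1 with the opposite sign. No background flags were given, so signals below the array median are treated as dim and not as absent.

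Groups were taken from the labels: PF68 or SWCNT, day 1 or day 7, with 2 arrays each. A linear model of the 4 group means was fitted to the log2 values of all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes; 4 residual and 1.81 prior degrees of freedom), since 2 arrays per group are too few for a spread of their own. The contrasts were: SWCNT against PF68 on each day, the difference between these, and day 7 against day 1 within each treatment. P-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, with a threshold of 0.05, and ± after a difference is the standard error from the moderated variance. The overlap of calls was tested with Fisher's exact test, two-sided. The 2 days have separate PF68 controls. Figures were drawn with matplotlib 3.10.9.

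Gene lists were fixed before the data were examined: 28 of processes and 24 of cell types that lung or neighbouring tissue could hold. Each was tested with camera at a preset correlation of 0.01, adjusted over the 52 lists of a contrast, with an estimated correlation and with fry beside it; fry tests whether a list's genes move, on balance, one way and compares them with no other genes. The genes named were also chosen by a rule fixed before the data were examined: on each day the 10 largest rises and the 10 largest falls among called genes whose 2 SWCNT arrays both lay on the same side of both PF68 arrays, for other contrasts 5 and 5, and up to 4 members with the largest differences of each list that passed camera. Predicted genes, immunoglobulin probe sets and pseudogenes were skipped in the former. Genes named outside the rule are marked as chosen after their values were seen. Such non-overlap of the 2 groups' arrays held for 53.2% of genes on each day, where chance gives 33.3%.

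The procedure was tested on simulated data with known changes in the 13853 genes. The noise was independent between genes and arrays, with an SD set by a gene's mean level alone. It held no spread of a gene's own and no shift shared by a group's arrays. The counts that follow check the procedure and are not error rates of these data. For day 1 it recovered 41 of 100 genes changed by 1 log2 unit and 87 of 100 changed by 2, with 7 false calls. For day 7 it recovered 39 and 82 of 100, with 4 false calls. Alternatives covered normalization, the filter, the choice of probe set, array weights, the variance model, replicate blocks, thresholds, the set test and leaving out arrays; those chosen after seeing the data were scaling to spikes, leaving out both day 1 arrays of a treatment, and counts without the genes of some lists. Random lists for the closing tests were drawn from genes of similar level. No column of other samples was present in the table.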

Results

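Gene expression was measured in the first lobe of the right lung of male ICR mice, an outbred strain, on 8 single-colour Affymetrix arrays. The mice had received 1 intratracheal instillation of 0.5 mg single-walled carbon nanotubes (SWCNT) in 50 µl of 0.1% Pluronic F-68 (PF68), a surfactant that keeps the tubes in suspension, or of PF68 without tubes. Lungs were taken on day 1 (the acute phase) or day 7 (the sub-chronic phase), with 2 arrays for each treatment and day. The study asked which transcripts respond to SWCNT relative to the solvent, in search of possible mechanisms of the lung lesions it had seen. The labels call the 2 arrays of a group biological replicates but do not name the animals, so p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

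All 8 arrays held the same set of sorted values, with a median of -0.628 and a range from -5.88 to 8.31 on a scale read as log2, so every difference below is relative to a common distribution. Pearson correlations across all probe sets (a description, since genes are not independent replicates) were 0.915 to 0.941 for the 4 pairs of arrays within a group and 0.891 to 0.931 for the 24 pairs between groups. The SD of the difference between the 2 arrays of a group was 0.922 to 1.01 in the dimmest 25% of probe sets and 0.240 to 0.283 in those above the 90th percentile. RNA quality signs and spikes moved with the groups. The 3′ minus 5′ signal of beta-actin, which rises as RNA is shortened, was 2.02 ± 0.02 (SD, n = 2) in PF68 day 1, 1.34 ± 0.03 (SD, n = 2) in SWCNT day 1, 3.27 ± 0.03 (SD, n = 2) in PF68 day 7 and 2.97 ± 0.04 (SD, n = 2) in SWCNT day 7. For Gapdh the same difference was 1.04, 0.716, 2.41 and 2.21 in that order, with SDs of 0.013, 0.051, 0.16 and 0.15 (n = 2 each). The bacterial hybridization spikes were higher by 0.20 in SWCNT than in PF68 on day 1 and lower by 0.61 on day 7, a log2 difference of -0.61. Scaling the arrays to these spikes, a choice made after seeing the data, moves every SWCNT minus PF68 difference by -0.20 on day 1 and by 0.61 on day 7. The median gene then differs by -0.22 and 0.63, against -0.02 and 0.02 as deposited, and the differences below are given relative to the deposited scale. The spikes are read on values already brought to a common distribution. Scaling to them therefore does not measure the amount of RNA in a lung, and counts with it show only how far calls depend on the scale.

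**Figure D1:**
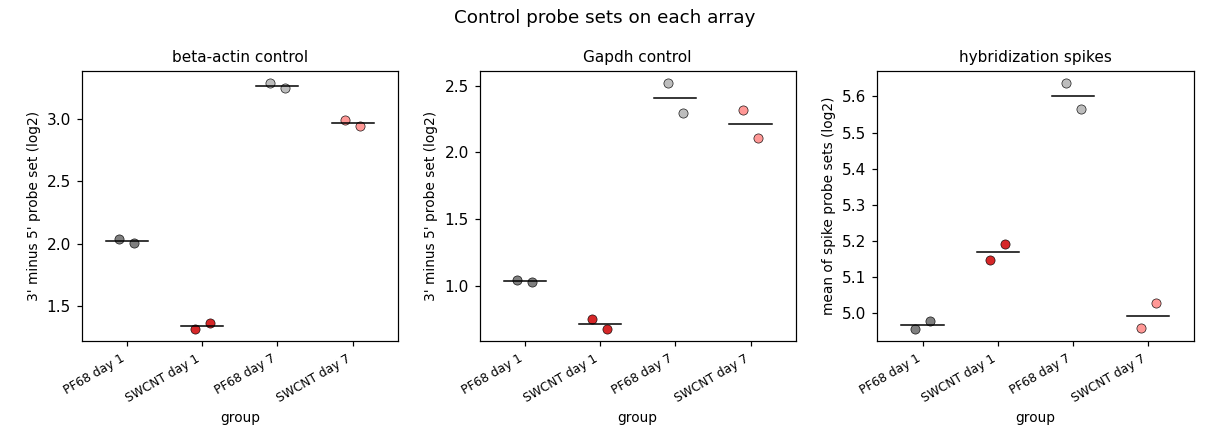
Control probe sets on each array: the 3′ minus 5′ log2 signal of beta-actin and of Gapdh and the mean log2 signal of the bacterial hybridization spikes (y axes), by group (x axes), with 1 point per array and a bar at the mean of the 2 arrays. The beta-actin difference lies at 1.34 in SWCNT day 1, 2.02 in PF68 day 1, 3.27 in PF68 day 7 and 2.97 in SWCNT day 7.

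On day 1, transcripts of striated muscle and of squamous epithelium had the largest rises in SWCNT lungs over PF68 lungs. Myh1, a fast-twitch myosin heavy chain, was higher by 6.41 ± 0.50 (log2 difference ± SE, n = 2 arrays per group; limma, adjusted p = 0.00676), and Acta1, the actin of skeletal muscle, by 5.13 ± 0.16 (35.1-fold; adjusted p = 0.000866). Krtdap and Krt4, which keratinizing and stratified epithelia express, were higher by 6.55 ± 0.84 and 4.90 ± 0.35 (3.81 in the other probe set of Krt4), and Nppa, the atrial natriuretic peptide, by 4.43 ± 0.20. Interferon-induced genes had the largest falls: the chemokine gene Cxcl10 was lower by 4.36 log2 units (-4.36 ± 0.30, adjusted p = 0.00484) and the antiviral gene Ifit1 by 4.14 (-4.14 ± 0.17, adjusted p = 0.00107). In all, 300 of 13853 genes passed an adjusted p of 0.05, 129 higher and 171 lower in SWCNT.

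The skeletal muscle list had 11 of its 18 measured genes higher, none lower and 7 not called, with a median difference of 2.90. In this list 16 were higher when adjusted over the list alone. Besides Myh1 and Acta1, Tnnc2 (5.26 ± 0.46) and Tnnt3 (4.56 ± 0.24), both troponin subunits of fast muscle, rose. Of the cardiac muscle list 15 of 27 were not called and 12 higher, including Myl1 (4.89 ± 0.53), Nppa and Ckm (3.20 ± 0.26). Ckm, a muscle creatine kinase that the skeletal muscle list also holds, differed by -0.40 in its other probe set. Skeletal muscle expresses Myl1 and other genes of the cardiac list too, so the rise of this list is not a separate sign of heart tissue. The cardiac list median was 1.03, with 21 higher adjusted over the list alone. Of the smooth muscle list 12 of 14 were not called and 2 higher, Des by 1.25 ± 0.15 and Acta2 by 0.80 ± 0.11. Its members had a median of 0.57, with 9 higher adjusted over the list alone. The adipose list had 10 of 14 not called and 4 higher: Car3 3.41 ± 0.11 (other probe set 2.34), the adipokine Adipoq 2.90 ± 0.21, Pck1 2.0 ± 0.24 and Fabp4 1.64 ± 0.12 (other probe set 0.87). The median of the list was 0.72, with 8 higher adjusted over the list alone. Camera gave adjusted p = 2.45e-21, 2.04e-19, 5.88e-07 and 3.28e-07 for these lists in that order, and adjusted p = 0.0115, 0.0177, 0.0484 and 0.13 with an estimated correlation, so that the adipose call was lost. Others of the 10 largest rises were Krt13 (5.00 ± 0.79, with other probe sets at 1.81 and 2.28), a keratin of stratified epithelia, and Mt4 (4.72 ± 0.18), a metallothionein of such epithelia. In the PF68 arrays Krtdap, Myh1, Tnnc2, Krt13, Krt4, Myl1, Mt4, Tnnt3 and Pck1 lay below the array median, where replicates scatter most. Counted from that median, the rises were 2.60 for Krtdap, 4.61 for Myh1, 4.14 for Tnnc2, 3.80 for Krt13, 4.56 for Krt4, 4.07 for Myl1, 2.95 for Mt4, 3.45 for Tnnt3 and 1.28 for Pck1. These lists moved with the SWCNT day 1 arrays, whose beta-actin 3′ minus 5′ signal was the lowest of the 4 groups at 1.34.

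In the interferon list 24 of 32 genes were lower, none higher and 8 not called, with a median of -1.57. In this list 30 were lower when adjusted over the list alone. Ifit2 (-3.46 ± 0.27), the GTPase genes Gbp6 (-3.26 ± 0.15), Igtp (-2.92 ± 0.12) and Irgm2 (-2.52 ± 0.21), the RNA sensor gene Dhx58 (-2.76 ± 0.12), Cmpk2 (-3.21 ± 0.13, with 1 other probe set at -0.87), Rsad2 (-2.62 ± 0.11, with 2 others at -3.34 and -0.95) and the transcription factor gene Irf7 (-2.47 ± 0.13) were among the 10 largest falls. In SWCNT Cxcl10 and Dhx58 lay below the array median, and counted from it their differences were -3.72 and -1.96. Camera gave adjusted p = 2.29e-33, and adjusted p = 0.00747 with an estimated correlation. The mean Ifit1 level was 4.93 in PF68 day 1, 0.78 in SWCNT day 1, 1.98 in PF68 day 7 and 1.97 in SWCNT day 7. The list of MHC class II antigen presentation had 8 of 11 not called and 3 lower: H2-Eb1 (-1.82 ± 0.15), H2-Aa (-1.70 ± 0.18, with 2 other probe sets at -0.75 and -0.61) and Ctss (-1.29 ± 0.10), a cathepsin that processes the invariant chain. Over the list the median was -0.76, with 10 lower adjusted over the list alone, and camera gave adjusted p = 2.24e-08 and adjusted p = 0.0484 with an estimated correlation.

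The NK cell, T cell, dendritic cell, monocyte and B cell lists were lower on day 1 in camera with the preset correlation only, and few of their genes were called. The NK cell list had 12 of 14 not called and 2 lower, among them the chemokine gene Ccl5 (-1.65 ± 0.17). Its median was -0.99, with 9 lower and 1 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.124 with an estimated correlation). The T cell list had 1 of 18 lower, Cd3d (-1.61 ± 0.18), and 17 not called. For this list the median was -0.66, with 3 lower adjusted over the list alone, and the camera call was lost (adjusted p = 0.124 with an estimated correlation). The dendritic cell list had 1 of 14 lower, Bst2 (-1.71 ± 0.14), itself induced by interferon, with 13 not called. The members' median was -0.48, with 4 lower adjusted over the list alone, and the camera call was lost (adjusted p = 0.15 with an estimated correlation). The monocyte list had 19 of 21 not called and 2 lower, Ms4a4c by -1.86 ± 0.17 and Plac8 by -1.34 ± 0.13. Here the median was -0.27, with 3 lower adjusted over the list alone, and the camera call was lost (adjusted p = 0.154 with an estimated correlation). The B cell list had 1 of 17 higher, Ighm (0.96 ± 0.16), with its 7 other probe sets all below 0, 1 lower, Jchain (-0.76 ± 0.12), the joining chain of antibodies, and 15 not called. The list median was -0.54, with 1 higher and 1 lower adjusted over the list alone, and the camera call was lost (adjusted p = 0.15 with an estimated correlation). The erythroid list had 1 of 7 lower, Slc4a1 (-2.13 ± 0.21, with 1 other probe set at -1.10), and 6 not called. Its members had a median of -0.35, with 3 lower adjusted over the list alone, and the camera call was lost (adjusted p = 0.154 with an estimated correlation). Other myeloid lists did not pass camera on day 1: neutrophil (median -0.05, adjusted p = 0.609), alveolar macrophage (0.03, 0.703), eosinophil (-0.07, 0.672) and mast cell (-0.47, 0.903).

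Of the hypoxia and glycolysis list 7 of 20 genes rose on day 1, none fell and 13 were not called. The median of the list was 0.71, with 13 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.103 with an estimated correlation). Tpi1 (1.32 ± 0.11), Aldoa (1.16 ± 0.11, with other probe sets from 0.32 to 1.02) and Pkm (1.15 ± 0.13) encode glycolytic enzymes that muscle also expresses, and Pfkl (1.59 ± 0.12) had other probe sets between -0.08 and 1.09. Acute phase genes had Saa3, a serum amyloid A gene, higher by 1.57 ± 0.13 and Itih4 lower (-1.35 ± 0.15), with 15 of 17 not called. Over the list the median was 0.44, with 6 higher and 1 lower adjusted over the list alone, and the camera call was lost (adjusted p = 0.154 with an estimated correlation). Of the alternative macrophage activation list 1 of 17 was higher, Retnla (1.14 ± 0.11), and 16 were not called. Its median was 0.42, with 3 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.098 with an estimated correlation). The collagen and matrix list had 4 of 35 higher, such as the proteoglycan gene Dcn (0.87 ± 0.12), and 31 not called. For this list the median was 0.16, or -0.04 with spike scaling, with 10 higher and 3 lower adjusted over the list alone, and the camera call was lost (adjusted p = 0.154 with an estimated correlation). The fibroblast list had 3 of 26 higher, among them Cox4i2 (1.30 ± 0.14), and 23 not called. The members' median was 0.18, or -0.02 with spike scaling, with 5 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.154 with an estimated correlation). Immediate early genes had 23 of 25 not called and 2 lower, Nr4a1 (-1.93 ± 0.20) and Nr4a2 (-1.69 ± 0.21, or -1.37 from the array median, with other probe sets from -1.09 to 0.53). Here the median was -0.27, with 9 lower and 2 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.124 with an estimated correlation). The mitosis list had 1 of 33 lower, Cdc20 (-1.07 ± 0.16, with 2 other probe sets at -0.46 and -0.18), and 32 not called. The list median was -0.37, with 5 lower adjusted over the list alone, and the camera call was lost (adjusted p = 0.124 with an estimated correlation).

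Of 52 lists, 19 passed camera's adjusted p of 0.05 on day 1, 9 up and 10 down, and 5 of these held with an estimated correlation: interferon, skeletal, cardiac and smooth muscle and MHC class II. Leaving out 1 of the 4 day 1 arrays left 30 to 34 called genes, 1 of the PF68 day 7 arrays 189 and 1 of the SWCNT day 7 arrays 127. The 4 day 1 arrays fitted alone gave 57. With spike scaling, chosen after seeing the data, 608 genes were called, 92 higher and 516 lower.

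**Figure D2:**
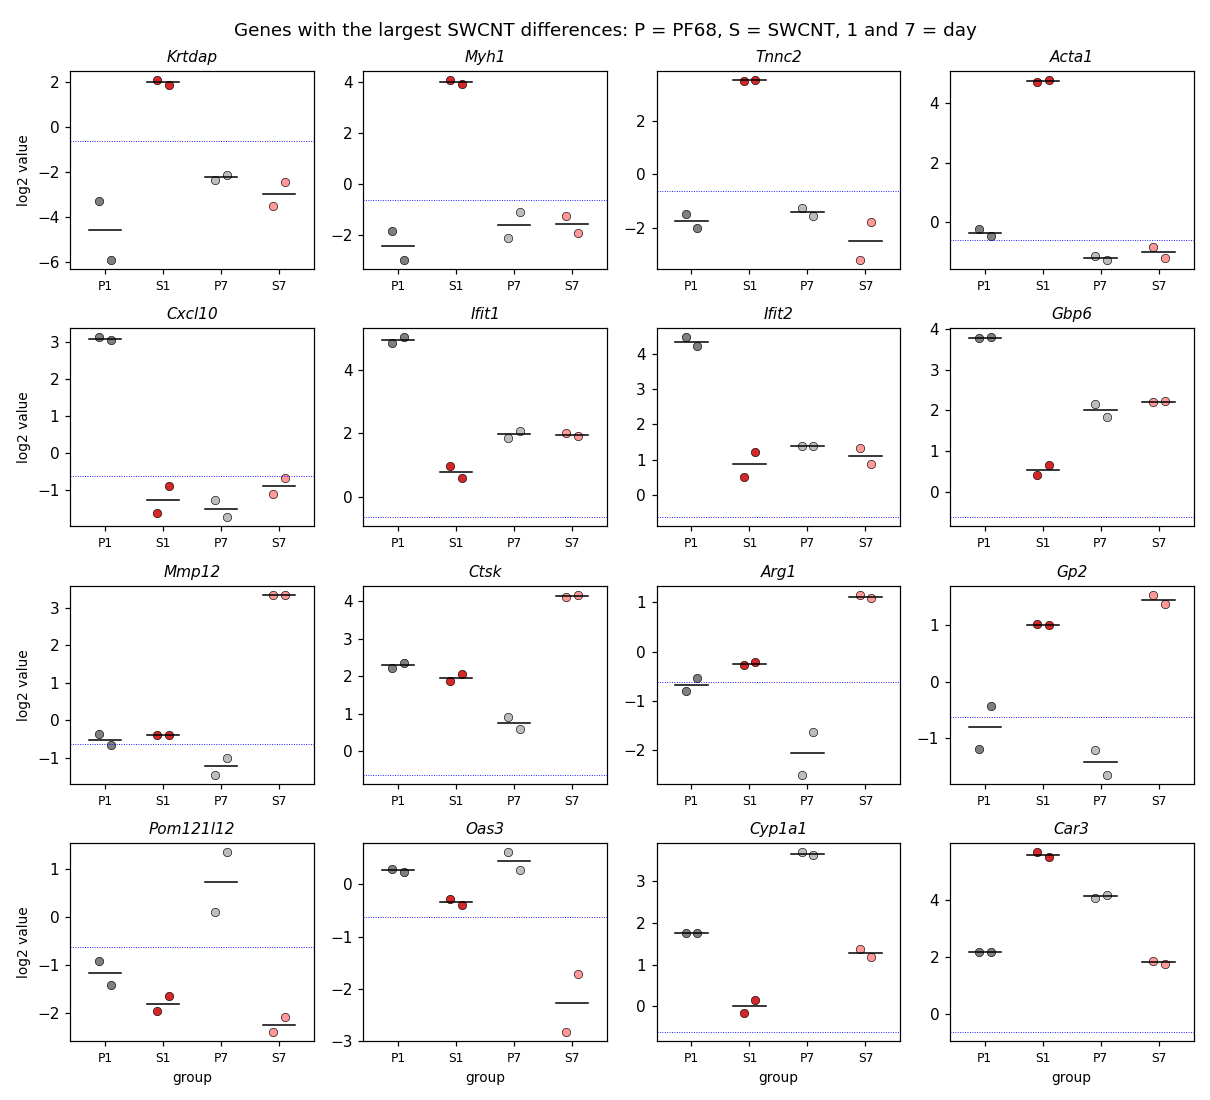
Log2 value (y axes) of the 4 genes with the largest rise and the 4 with the largest fall on day 1 (upper rows) and on day 7 (lower rows) in each group (x axes; P is PF68, S is SWCNT, 1 and 7 are the days), with 1 point per array, a bar at the mean of the 2 arrays and a dotted line at the array median of -0.628. Acta1 lies at 4.77 on average in SWCNT day 1 and below 0 in the other groups, Ifit1 at 4.93 in PF68 day 1, and Mmp12 at 3.33 in SWCNT day 7.

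On day 7, Mmp12 and Ctsk had the largest rises in SWCNT lungs. Mmp12, the elastase of macrophages, was higher by 4.57 ± 0.18 (log2 difference ± SE, n = 2 arrays per group; limma, adjusted p = 0.00419), and Ctsk, the collagen-cleaving cathepsin K, by 3.39 ± 0.15 (10.5-fold; adjusted p = 0.00419). Arg1, arginase of alternatively activated macrophages, was higher by 3.18 ± 0.29, and Gpnmb, a glycoprotein of lipid-loaded macrophages, by 2.23 ± 0.12. The lists of alternative macrophage activation and of monocytes did not pass camera on day 7. Cyp1a1, a cytochrome of xenobiotic metabolism, was lower (-2.39 ± 0.14, adjusted p = 0.00898), as was Mmp8, the collagenase of neutrophils (-2.0 ± 0.16, adjusted p = 0.0152). In all 302 genes passed, 194 higher and 108 lower in SWCNT.

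Of the list of granuloma-associated macrophage genes, 9 of 25 were higher, none lower and 16 not called. Its members had a median of 0.68, with 17 higher adjusted over the list alone, and camera gave adjusted p = 9.43e-11 and adjusted p = 0.0755 with an estimated correlation. Its 4 largest differences were those of Mmp12, Ctsk, Trem2 (2.41 ± 0.52, adjusted p = 0.0728, not called) and Gpnmb, and the scavenger receptor gene Msr1 was higher by 2.23 ± 0.36. The other probe sets of Msr1 differed by 0.09 to 1.46, and that of Trem2 by 0.66. The lysosome list had 11 of 29 higher, 1 lower and 17 not called. The median of the list was 0.42, with 15 higher and 1 lower adjusted over the list alone, and camera gave adjusted p = 1.68e-07 and adjusted p = 0.0755 with an estimated correlation. Cd68, a lysosomal membrane protein of macrophages, rose by 1.61 ± 0.10, Atp6v0d2, a proton pump subunit, by 1.11 ± 0.13 (other probe set 0.38), and the cathepsin gene Ctsz by 1.08 ± 0.11. The alveolar macrophage list shares Ctsk, Atp6v0d2, Cd9 and other genes with these lists and had 17 of 21 not called and 4 higher, Olr1, a scavenger receptor gene, among them (1.34 ± 0.15). Over the list the median was 0.38, with 11 higher and 1 lower adjusted over the list alone, and camera gave adjusted p = 0.0876 with an estimated correlation.

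The acute phase list had 12 of 17 not called on day 7 and 5 higher: Lcn2 1.81 ± 0.14, Saa3 1.78 ± 0.13 and the metallothionein gene Mt2 1.70 ± 0.13 among them. Its median was 0.63, with 8 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.153 with an estimated correlation). In the CC chemokine list 13 of 16 were not called and 3 rose, such as Ccl3 (1.77 ± 0.19, or 0.61 from the array median, below which its PF68 arrays lay) and Ccl9 (1.39 ± 0.11). For this list the median was 0.39, with 5 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.153 with an estimated correlation). The list of CXC chemoattractants did not pass camera (median 0.05, adjusted p = 0.986), with 1 of 14 higher, Cxcl5, and 13 not called. None of 16 complement genes passed, C3ar1 being at 1.63 ± 0.29 (other probe sets 0.37 and 0.84). The members' median was 0.31, with 2 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.181 with an estimated correlation). None of 11 inflammasome genes passed either, Casp1 being at 0.95 ± 0.24. Here the median was 0.26, with 2 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.163 with an estimated correlation). The collagen and matrix list had 28 of 35 not called and 7 higher, such as Fn1 (fibronectin) 1.46 ± 0.10, whose other probe set differed by 0.04, Eln (elastin) 1.06 ± 0.10 and the crosslinking enzyme gene Lox 1.52 ± 0.10, whose 2 other probe sets differed by -0.05 and 1.82. The list median was 0.17, with 7 higher and 1 lower adjusted over the list alone, and the camera call was lost (adjusted p = 0.153 with an estimated correlation). In the hypoxia and glycolysis list 17 of 20 were not called and 3 rose, including Ankrd37 (2.25 ± 0.17) and Pgam1 (1.02 ± 0.14). Its members had a median of 0.42, with 12 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.153 with an estimated correlation). In the mitosis list 1 of 33, Top2a (1.46 ± 0.23), rose and 32 were not called. The median of the list was 0.43, with 10 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.0976 with an estimated correlation).

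The xenobiotic metabolism list on day 7 had 7 of 23 genes lower, none higher and 16 not called. Over the list the median was -0.50, or 0.11 with spike scaling, with 17 lower and 2 higher adjusted over the list alone, and camera gave adjusted p = 1.43e-08 and adjusted p = 0.0876 with an estimated correlation. Aldh3a1 (-1.85 ± 0.16) and Cyp2e1 (-1.58 ± 0.13) fell beside Cyp1a1. The neutrophil list had 6 of 20 lower, 1 higher and 13 not called: Ngp, a granule protein gene, fell (-1.47 ± 0.11), and of genes chosen after their values were seen S100a8 (-1.16 ± 0.10) fell while Ltf (1.32 ± 0.16), the lactoferrin gene that airway glands also express, rose. Its median was -0.64, or -0.03 with spike scaling, with 9 lower and 3 higher adjusted over the list alone, and camera gave adjusted p = 8.43e-05 and adjusted p = 0.0882 with an estimated correlation. The club cell list had 4 of 19 lower, 1 higher and 14 not called, with the airway secretory genes Bpifa1 (-1.38 ± 0.13) and Bpifb1 (-1.30 ± 0.12) lower and Retnla (1.02 ± 0.11) higher. For this list the median was -0.26, or 0.35 with spike scaling, with 8 lower and 1 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.0976 with an estimated correlation). The endothelial list had 2 of 29 lower, Plvap (-1.05 ± 0.15) and Flt1 (-0.97 ± 0.15), and 27 not called. The members' median was -0.23, or 0.38 with spike scaling, with 8 lower and 1 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.0976 with an estimated correlation). The adipose list had 1 of 14 lower, Car3 (-2.30 ± 0.11, with 1 other probe set at -0.82), and 13 not called. Here the median was -0.45, or 0.16 with spike scaling, with 7 lower and 1 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.284 with an estimated correlation). The B cell list had 1 of 17 lower and 16 not called. The list median was -0.44, or 0.17 with spike scaling, with 4 lower and 1 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.153 with an estimated correlation). The NK cell list had none of 14 called. Its members had a median of -0.35, or 0.26 with spike scaling, with 1 lower adjusted over the list alone, and the camera call was lost (adjusted p = 0.248 with an estimated correlation). The platelet list had 1 of 12 lower, Gp1bb (-0.88 ± 0.13, with 1 other probe set at 0.48), with 11 not called. The median of the list was -0.33, or 0.28 with spike scaling, with 2 lower and 1 higher adjusted over the list alone, and the camera call was lost (adjusted p = 0.153 with an estimated correlation).

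Others among the 10 largest rises were Gp2 (2.88 ± 0.28), a glycoprotein of secretory granules, Alkbh8 (2.72 ± 0.37), Serpinb2 (2.51 ± 0.41), an inhibitor of plasminogen activators, and Ang3 (2.11 ± 0.20), a ribonuclease of the angiogenin family. Among the 10 largest falls were Pom121l12 (-2.97 ± 0.42), Oas3 (-2.72 ± 0.36), the gluconeogenic enzyme gene Fbp1 (-1.80 ± 0.28), Rasgrf1 (-1.80 ± 0.26), Tfr2 (-1.77 ± 0.27) and Golt1b (-1.76 ± 0.18), whose other probe set differed by 0.28. Both arrays of the lower group lay below the array median for 9 of the 20 genes with the largest rises and falls. Counted from that median the differences were 3.96 for Mmp12, 1.74 for Arg1, 2.08 for Gp2, 0.59 for Alkbh8, 0.79 for Serpinb2, -1.35 for Pom121l12, -1.07 for Oas3, -0.81 for Tfr2 and -1.45 for Golt1b. For 4 others 1 of the 2 arrays lay below it, with 2.06 for Ankrd37, 1.87 for Msr1, -1.60 for Fbp1 and -1.77 for Rasgrf1. Of 52 lists, 18 passed camera on day 7, 10 up and 8 down, and none held with an estimated correlation, the smallest adjusted p being 0.0755. The count of 302 genes was 0 without either SWCNT day 7 array, 18 and 6 without a PF68 day 7 array, 7 without either SWCNT day 1 array and 4 without either PF68 day 1 array. The 4 day 7 arrays fitted alone called 0 genes in limma, with 2490 at an unadjusted p under 0.05. Array weights, which were lowest for the PF68 day 7 arrays (0.647), gave 102 genes. With spike scaling, chosen after seeing the data, 7056 genes were called, 6985 higher and 71 lower.

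**Figure D3:**
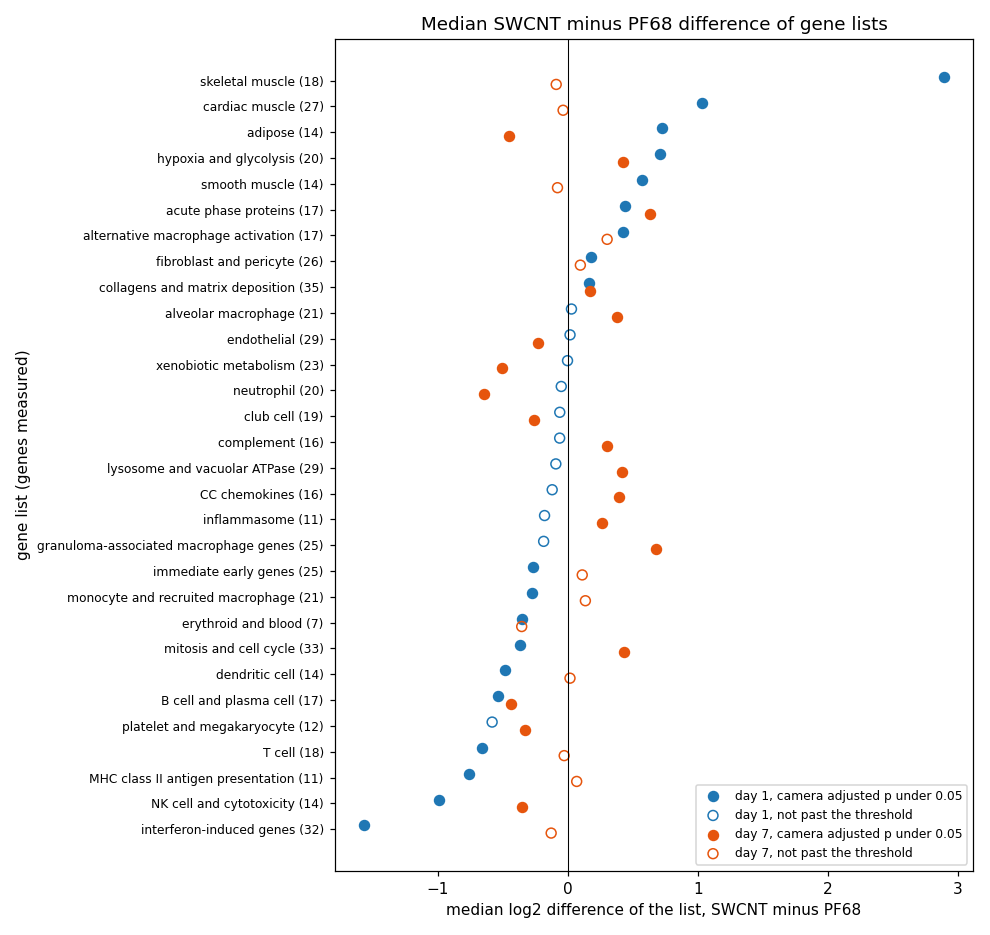
Median log2 difference between SWCNT and PF68 (x axis) of the gene lists that passed camera on at least 1 of the days (y axis, with the number of measured genes), on day 1 (blue) and day 7 (orange); filled points passed an adjusted p of 0.05 with the preset correlation. The skeletal muscle list lies at 2.90 on day 1 and -0.09 on day 7, the interferon list at -1.57 and -0.13, and the granuloma-associated macrophage list at -0.18 and 0.68. With spike scaling the medians of 2 called lists change sign on day 1 and of 7 on day 7.

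The SWCNT effect differed between the days for 325 of 13853 genes, 196 with a higher and 129 with a lower difference on day 7 (limma, adjusted p of 0.05 for the difference itself). The macrophage genes Mmp12 (4.45 ± 0.26), Ctsk (3.73 ± 0.21) and Gpnmb (2.84 ± 0.17) had a higher SWCNT effect on day 7, each with adjusted p = 0.00513. So did the interferon-induced genes Cxcl10 (4.98 ± 0.43) and Ifit1 (4.13 ± 0.24), both lower in SWCNT on day 1, and the water channel gene Aqp3 (5.31 ± 0.76), which passed on neither day by itself. Lower on day 7 were the effects on Krtdap (-7.30 ± 1.18), Myh1 (-6.40 ± 0.70), Tnnc2 (-6.33 ± 0.66), Car3 (-5.71 ± 0.16) and Mt4 (-5.02 ± 0.26). All of these but Ctsk, Gpnmb, Ifit1 and Car3 had groups below the array median. Counted from that median the values were 2.04 for Aqp3, 3.72 for Cxcl10, 3.85 for Mmp12, -2.60 for Krtdap, -4.61 for Myh1, -4.14 for Tnnc2 and -2.95 for Mt4. Camera called 26 of 52 lists for the difference, and 5 held with an estimated correlation. The interferon list had 20 of 32 genes higher and 12 not called, with a median of 1.42, 23 higher and 1 lower adjusted over the list alone, and adjusted p = 0.0211 with an estimated correlation. For granuloma-associated macrophage genes 7 of 25 were higher, 1 lower and 17 not called, with a median of 0.92, 17 higher and 1 lower adjusted over the list alone, and adjusted p = 0.0293 with an estimated correlation. Of lysosome genes 8 of 29 were higher and 21 not called, with a median of 0.44, 14 higher and 1 lower adjusted over the list alone, and adjusted p = 0.0411 with an estimated correlation. Skeletal muscle had 10 of 18 lower and 8 not called, with a median of -3.06, 16 lower adjusted over the list alone, and adjusted p = 0.0211 with an estimated correlation. Cardiac muscle had 5 of 27 lower and 22 not called, with a median of -1.10, 17 lower adjusted over the list alone, and adjusted p = 0.0293 with an estimated correlation. Leaving out 1 array left 3 to 20 genes for the day 1 arrays, 74 and 41 for those of PF68 day 7 and 19 and 23 for those of SWCNT day 7. Chosen after seeing the data, a count without the genes of the muscle, fat and squamous lists gave 212 (143 higher, 69 lower) and spike scaling 6745 (6647 higher, 98 lower).

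**Figure D4:**
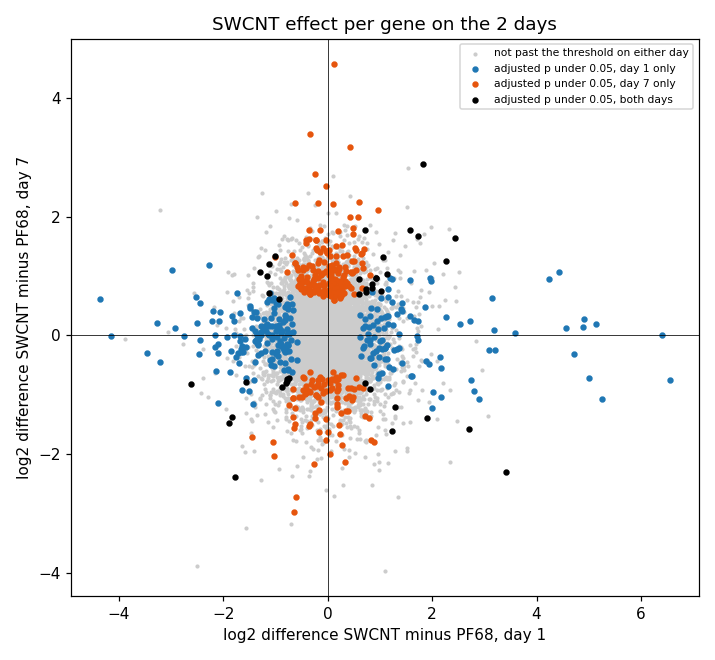
Log2 difference between SWCNT and PF68 per gene on day 1 (x axis) and day 7 (y axis) for 13853 genes, coloured by whether adjusted p was under 0.05 on day 1 (blue), on day 7 (orange), on both days (black) or on neither (grey). Across genes the differences had a Pearson r of 0.002.

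Between the days, 17 genes were called higher on both, against 1.81 for independent lists (Fisher's exact test, two-sided, p = 2.72e-12), and 10 lower on both, against 1.33 (p = 8.62e-07, Fisher's exact test). Saa3 and Retnla were higher on both days, and of genes chosen after their values were seen so were Cxcl5 (1.74 and 1.67, or 1.20 and 0.01 from the array median, below which its PF68 arrays lay), a neutrophil chemoattractant, and Lrg1 (0.72 and 1.78). Cyp1a1 (-1.76 on day 1), Ngp and H2-Eb1 were lower on both. In opposite directions 7 genes were higher on day 1 and lower on day 7, among them Car3, Cyp2e1 and Bpifa1 (Fisher's exact test, p = 6.59e-05), and 6 lower on day 1 and higher on day 7, among them Ctss and the chemokine gene Ccl8 (Fisher's exact test, p = 0.0333). Both days share 1 estimate of each gene's spread, so a gene with little spread tends to be called on both, and independence is not the value expected without a shared response. Among the 40 genes called on both days, where this cancels, 27 had the same direction and 13 the opposite (Fisher's exact test of direction, chosen after seeing the data, p = 0.0531). Over all genes the differences on the 2 days had a Pearson r of 0.002 and a Spearman rho of 0.007 across genes, which are not independent replicates. The shared calls were 10 at a log2 difference of at least 1 and 3 without a filter on dim probe sets.

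In PF68 lungs, 2455 genes differed between day 7 and day 1, 1228 higher and 1227 lower on day 7, a comparison of the vehicle alone over time. Interferon-induced genes had the largest group change: 10 of 32 were not called and 22 lower on day 7, with Cxcl10 at -4.61 ± 0.30. Over the list the median was -1.37, with 25 lower adjusted over the list alone, and camera gave adjusted p = 1.05e-15 and adjusted p = 0.0325 with an estimated correlation. Of glucocorticoid-induced genes 13 of 19 were lower, 1 higher and 5 not called. Their median was -0.63, with 14 lower and 1 higher adjusted over the list alone, and camera gave adjusted p = 0.0828 with an estimated correlation. Of collagen and matrix genes 16 of 35 were lower, 1 higher and 18 not called. For this list the median was -0.48, with 18 lower and 1 higher adjusted over the list alone, and camera gave adjusted p = 0.101 with an estimated correlation. Other large differences were those of Ankrd37 (-3.48 ± 0.17), Iqcf1 (-3.64 ± 0.53), Aqp3 (-3.43 ± 0.54) and Trim30d (-3.36 ± 0.31), and the adrenaline-forming enzyme gene Pnmt (3.23 ± 0.47), Aldh8a1 (2.87 ± 0.47), Tex33 (3.65 ± 0.94), Sox9 (3.59 ± 0.92) and Mup3 (2.73 ± 0.61). Of these all but Ankrd37 and Pnmt had both arrays of the lower group below the array median, as had Cxcl10. Counted from it the differences were -3.72 for Cxcl10, -2.07 for Iqcf1, -1.67 for Aqp3, -1.12 for Trim30d, 1.95 for Aldh8a1, 1.83 for Tex33, 2.08 for Sox9 and 1.47 for Mup3, and -3.29 for Ankrd37, with 1 array below. The 3′ minus 5′ signal of beta-actin moved with the same groups, from 2.02 on day 1 to 3.27 on day 7. The count was 30 and 0 without a PF68 day 1 array, 1410 and 1250 without a PF68 day 7 array, and 1523 without either SWCNT day 7 array. With the 4 PF68 arrays alone it was 0 in limma, where 4063 genes had an unadjusted p under 0.05. With spike scaling 6302 genes were called, 145 higher and 6157 lower.

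In SWCNT lungs, 2257 genes differed between the days, 1329 higher and 928 lower on day 7. Muscle genes were lower on day 7: 15 of 18 genes of the skeletal muscle list and 21 of 27 of the cardiac list (1 higher), with 3 and 5 not called. Their medians were -2.83 and -1.64, with adjusted p = 0.0363 for both with an estimated correlation. Adjusted over the list alone 17 and 23 were lower, and 1 cardiac gene was higher. Tnnc2 was at -6.01 ± 0.46, Acta1 at -5.80 ± 0.16, Myl1 at -5.25 ± 0.53 and Krt4 at -5.22 ± 0.35. Granuloma-associated macrophage genes had 11 of 25 not called, 2 lower and 12 higher, with Mmp12 at 3.73 ± 0.18, Trem2 at 2.5 ± 0.52 and Gpnmb at 2.21 ± 0.12. The members' median was 0.38, with 14 higher and 3 lower adjusted over the list alone, and camera gave adjusted p = 0.0682 with an estimated correlation. Endothelial genes had 19 of 29 not called, 1 higher and 9 lower, such as Emcn (-2.04 ± 0.14). Here the median was -0.36, with 13 lower and 1 higher adjusted over the list alone, and camera gave adjusted p = 0.0409 with an estimated correlation. Rgs1, H2-Eb2 and Cblif were higher on day 7, by 2.36 ± 0.18, 2.42 ± 0.52 and 2.65 ± 0.44. Their SWCNT day 1 arrays lay below the array median, and counted from it the rises were 1.56, 0.26 and 0.04. So did those of Trem2, with 2.11, and the day 7 arrays of Tnnc2 (-4.14), Acta1 (-5.39), Myl1 (-4.07) and Krt4 (-4.56). The beta-actin 3′ minus 5′ signal rose with the same arrays, from 1.34 to 2.97. Leaving out 1 array gave 473 and 370 genes for SWCNT day 1 and 248 and 91 for SWCNT day 7, and 1375 for either PF68 day 1 array. The 4 SWCNT arrays alone gave 7. With spike scaling 2966 were called, 2371 higher and 595 lower.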

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

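The test of the difference between the days and that of the unseen squamous genes were set before their values were seen, while the tests of SWCNT acting on the lung's own cells, of an elevated PF68 level and of dilution, and the repeats marked so, were chosen after the results they bear on. The first of these singled out the values below, which are log2 differences of the SWCNT effect, day 7 minus day 1 (limma for genes, camera for lists, adjusted p of 0.05); in all 325 genes passed.

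The first pattern weighed is the rise of muscle, squamous epithelium and fat genes in SWCNT day 1. Its genes differ between the days by -7.30 for Krtdap, -6.40 for Myh1, -6.33 for Tnnc2, -5.02 for Mt4, -4.94 for Acta1, -4.75 for Myl1, -4.63 for Krt4, -4.44 for Tnnt3, -3.36 for Nppa and -5.71 for Car3. Counted from the array median, below which the other 3 groups of most of these genes lay, they were -2.60 for Krtdap, -4.61 for Myh1, -4.14 for Tnnc2, -2.95 for Mt4, -5.13 for Acta1, -4.07 for Myl1, -4.56 for Krt4 and -3.45 for Tnnt3. Its lists differ by medians of -3.06 (skeletal muscle), -1.10 (cardiac muscle), -0.55 (smooth muscle) and -1.18 (adipose). These values include day 7 differences, of -2.30 for Car3 and a median of -0.45 for the adipose list. Not all day 7 differences were falls: Nppa had a mean of 0.15 in PF68 day 7 and 1.22 in SWCNT day 7. Myl7 of the cardiac muscle list, chosen after its values were seen, was called higher on both days. Averaged over the 6 arrays outside SWCNT day 1, 7 of 18 skeletal muscle genes lay at or above the array median. So did 24 of 27 cardiac, 14 of 14 smooth muscle and 12 of 14 adipose genes. The cardiac, smooth muscle and adipose lists thus held signal in the other groups too.

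Tissue from beside the lung in the SWCNT day 1 RNA could give such a rise, and the prediction was that squamous genes not looked at before would rise too: 19 such genes had a median of 0.39, against -0.25 to 0.23 for random lists of similar level, and Sbsn, Dmkn and Fam25c were called higher. Without the filter on dim probe sets, a repeat chosen after seeing the data, 27 such genes had a median of 0.39, against -0.23 to 0.21. The squamous genes thus rose as this explanation predicted. Genes of the same tissue can rise together under any cause, so the result cannot tell it from SWCNT acting on the lung's own cells. Muscle and fat genes were not part of the test. SWCNT acting on the lung's own cells may be short-lived: the skeletal muscle list had a median of -0.09 on day 7, which cannot tell, since the rise and the SWCNT day 1 group cannot be separated. Leaving out the genes of these lists, chosen after seeing the data, removed 38 called genes, all higher, and with p-values adjusted over the rest 204 of the other 262 stayed called (71 higher, 133 lower). The 58 others (20 higher, 38 lower) no longer passed, and 22 of the 24 interferon list genes did.

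The second pattern is the interferon list, lower in SWCNT than in PF68 on day 1. Its median differs between the days by 1.42, and Cxcl10 by 4.98, Ifit1 by 4.13, Gbp6 by 3.47, Irgm2 by 3.17, Ifit2 by 3.16, Igtp by 3.05, Cmpk2 by 2.76, Dhx58 by 2.75, Irf7 by 2.15 and Rsad2 by 1.80. Counted from the array median Cxcl10 and Dhx58 were at 3.72 and 1.95.

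An elevated level in the PF68 day 1 arrays could produce it, and the values it needs are there: PF68 day 1 lay above the mean of the day 7 groups by a median of 1.61 (31 of 32 genes above), while SWCNT day 1 differed from that mean by -0.22 (quartiles -0.59 and 0.04; 9 of 32 above). These values restate the fall of the list over time in PF68 (-1.37), so they describe where the change lies and add no separate support. Dilution of lung RNA by RNA of other tissue is excluded as the sole cause, since the alveolar type 2 and endothelial lists had day 1 medians of -0.17 and 0.02, against -1.57 for the interferon list. Whether SWCNT lower an interferon response to the instillation was not tested, as no untreated lung is among the samples.

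Other genes differ between the days by 4.45 (Mmp12), 3.73 (Ctsk), 2.84 (Gpnmb), 2.76 (Arg1), 1.65 (Ankrd37), 5.31 (Aqp3), -2.05 (Mmp8), -2.13 (Aldh3a1), -2.68 (Rasgrf1) and -2.59 (Golt1b). Counted from the array median Aqp3 was at 2.04, Arg1 at 1.41, Mmp12 at 3.85, Ankrd37 at 1.46, Golt1b at -2.26 and Rasgrf1 at -2.66. Other lists with a higher median effect on day 7 are granuloma-associated macrophages (0.92), dendritic cells (0.69), MHC class II (0.66), T cells (0.65), CC chemokines (0.60), mitosis (0.53), monocytes (0.52), alveolar macrophages (0.45), lysosome (0.44), the inflammasome (0.37), immediate early genes (0.37), complement (0.29) and alveolar type 2 cells (0.29). Lists with a lower one are mesothelium (-0.44), xenobiotic metabolism (-0.41), heat shock (-0.36), neutrophils (-0.35), club cells (-0.30), endothelium (-0.27), alveolar type 1 cells (-0.16) and Nrf2 (-0.14). Of these only the granuloma-associated macrophage and lysosome lists passed with an estimated correlation, and the medians of 9 of the 26 lists change sign with spike scaling.

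Probe sets that match several gene symbols are outside the comparisons of the report, and 56 of 655 were called on day 1 (20 higher, 36 lower) and 60 of 655 on day 7 (41 higher, 19 lower); of 3404 with no gene listed 0 were called on either day.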

How the results depend on the processing

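The calls rest on 2 arrays per group, and dim signals limit them: counts rose with fewer dim genes tested and fell with more. Values follow in the order day 1, day 7, their difference, PF68 over time and SWCNT over time, against 300, 302, 325, 2455 and 2257 called genes. Of the alternative values for named genes 3091 kept direction and side of the threshold, 1040 became weaker, 88 stronger and 9 reversed; for called lists 759 kept both, 44 became weaker and 10 medians changed sign. These tallies include repeated quantile normalization and median centring, which changed nothing. Replicate blocks, the variance model, array weights, fits of only the 4 arrays compared and leaving out arrays of other groups keep the group means compared. No gene's direction or list's median could change sign there, so the few reversals do not measure how stable directions are. An estimated correlation is counted apart below. Leaving out 1 array, the lone array of the group being assumed to vary like the others, gave 30 to 189, 0 to 18, 3 to 74, 0 to 1841 and 91 to 2319 genes and 33 to 40 lists, against 37. A log2 difference of at least 1 gave 195, 152, 301, 708 and 660 (27 shared calls became 10), and an adjusted p under 0.01 gave 64, 8, 24, 331 and 455. Without a filter on dim probe sets the counts were 123, 24, 50, 1407 and 1317 (3 shared), and with a filter at the 75th percentile, where fewer genes are tested, 945, 1330, 1164, 3365 and 3266. The mean of all probe sets of a gene gave 193, 97, 157, 1457 and 1383, and the probe set with the largest SD 142, 56, 66, 1825 and 1701. With only the 4 arrays compared, which leaves fewer degrees of freedom, the counts were 57, 0, 0 for PF68 over time and 7 for SWCNT over time (0 shared, as day 7 had none to share). A trend with robust variances gave 1254, 1617, 1382, 3568 and 3411, array weights 419, 102, 294, 2044 and 2674, and cyclic loess 307, 283, 323, 2528 and 2229. The weights were 0.647 for the PF68 day 7 arrays and 0.999 to 1.281 for the others, which the common spread of the main model does not allow for. For other changes the cause was not tested. Repeating quantile normalization or centring on the median left the values as they were, so neither is evidence, and another log offset was not applicable to values already on a log scale.

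The replicate numbers do not pair the arrays (r of -0.006 to 0.012 between deviations, 6 pairs of groups). A replicate block within day gave 3, 0, 0, 0 and 0 genes (2242, 2823, 2539, 3489 and 3395 at an unadjusted p under 0.05), and a replicate block across days 102, 15, 30, 1878 and 1726.

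Chosen after seeing the data, spike scaling gave 608, 7056, 6745, 6302 and 2966 genes. Without both SWCNT day 1 arrays day 7 had 7 genes and PF68 over time 1841, and without both PF68 day 1 arrays day 7 had 4 and SWCNT over time 1375. Without the muscle, fat and squamous genes day 1 had 204 and the difference 212, and without the interferon list day 1 had 232. Medians of lists that changed sign with spike scaling, which moves every gene of a comparison alike, were collagens (-0.0395) and fibroblasts (-0.0226) on day 1, and xenobiotic metabolism (0.11), NK cells (0.26), B cells (0.17), club cells (0.35), endothelium (0.38), fat (0.16) and platelets (0.28) on day 7. That of the day 1 T cell list changed with the filter at the 75th percentile (0.0016), where fewer genes are tested. For lists, 5 of 37 calls passed with an estimated correlation, and fry, which compares a list with no other genes, called 74.

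Reversed on day 1 were Ighm (-0.49), Scara5 (-0.46) and Myh11 (-0.033) with the mean of probe sets, and Ighm (-2.11) and Nr4a2 (0.53) with the largest SD, as their other probe sets differ. Reversed on day 7 were Masp1 (-0.93, and 2.29 without replicate 2) without SWCNT day 7 replicate 1, where the cause was not tested, and Car4 (0.0886), Aplnr (0.0888) and Gp9 (0.0313) with spike scaling, which adds 0.61 to every gene.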

Other observations

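Lists of tissues found beside or around the lung were added after the rise of Krt4, Krt13 and Krtdap had been seen, and in the last paragraph the test of separate animals and the way random lists were matched were chosen after results had been seen, while the test of the same source was set before. Of 26 measured genes of stratified squamous epithelium 10 were higher on day 1, 0 lower and 16 not called, with a median of 1.22, against -0.23 to 0.21 for random lists of similar level. This median includes genes already seen to rise, so it adds no support. The 19 not looked at before had a median of 0.39, against -0.25 to 0.23, with 3 called higher. The called genes include Sbsn and Dmkn, secreted proteins of keratinizing epithelium, not looked at before. Rptn and Crct1, of the cornified layer, had been looked at. On average over the 6 arrays outside SWCNT day 1, 13 of the 26 lay at or above the array median. On day 7 the list had 0 called genes and a median of -0.29, against -0.26 to 0.26. The peripheral nerve list (11 measured, 0 called) had a day 1 median of 0.24, against -0.29 to 0.26, and the cartilage list (5 measured, 0 called) 0.18, against -0.49 to 0.48.

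The third pattern weighed is that the 2 arrays of a group differ little in what the lists measure. If both arrays carry RNA of the same source, lists should differ between them no more than random lists do. That may be so: by the signed mean difference of a list, 2.9% of 208 lists and groups lay outside the 95% range of random lists, as the explanation needs. Similar animals could give the same. Between SWCNT and PF68 the share was 41.3% of 104, but it is not a like measure. It takes differences of means of 2 arrays, which are less noisy, and random lists matched on the mean of all arrays. With that matching the share between the 2 arrays of a group was 4.8%. The lists share genes and come from the same 8 arrays, so these shares are given without intervals. Separate animals with their own amounts of other tissue cannot be told from this. Between the SWCNT day 1 arrays the skeletal muscle list had a mean absolute log2 difference per gene, without regard to sign, of 0.29. Random lists had a median of 0.21 and an upper limit of 0.35. Matched on the mean of all arrays, the values were 4.8%, and 0.29 against 0.47 and 0.71, at percentile 1.8. The skeletal muscle list had a median level of 2.16 in SWCNT day 1, against -1.07 in the other 6 arrays. Genes matched on the mean of all arrays are therefore dimmer in SWCNT day 1 and scatter more. The low percentile follows from that matching and excludes nothing, and separate animals with similar amounts could also differ little.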
